A study of Homo sapiens with 598 samples.

How the data were processed

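The samples are 598 single cells of A673/TR/shEF, a Ewing sarcoma line with a doxycycline-inducible hairpin against EWSR1-FLI1, 383 from culture and 215 from xenografts. Per the labels' protocols, cells were captured on C1 microfluidic chips and their full-length cDNA was made into libraries with Nextera XT, without molecular identifiers. The deposited table holds raw read counts per gene, 1 column per cell, with no normalization, and its columns were matched to samples by the cell names in the titles. The submitters' processing notes name TopHat2 2.0.6, HTSeq 0.5.3p9 and DESeq, and the builds hg19 and GRCh37, with no role or order, and the cell filters applied before deposit are not given in the sources used here. The reference at hand was of another build (GRCh38), so it served for a check of names alone, and no coordinates are given. Of 56764 gene identifiers in the table, 21786 had a count in any cell and 49995 matched the reference. The table's own symbols were used; 110 identifiers without a symbol held 0.0595% of the counts and kept their identifiers in the sums and tests, 71 of them being known to the reference. Where a symbol stood for several identifiers, the one with the most counts kept the symbol and the other 4917 were named by their identifiers. Reads of near-identical genes and of overlapping antisense genes could not be told apart, since no use of strand is given. The 13 mitochondrially encoded genes, meant as a measure of RNA quality, had 0 counts in all cells, so that list has no value and the share of counts on MALAT1 is given in its place, a measure chosen after the zeros were seen.

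Cells had to hold at least 50000 counts and 1000 genes, which removed 0 cells, so leaving this filter out is no separate alternative. No doublet caller was run, since none suits chip-captured cells of 1 line. Of all pairs of cells, 3 had a correlation of log counts above 0.95 (0.987, 0.984 and 0.981, the next pair 0.836), and their counts differed little more than by sampling noise, with a chi-square per degree of freedom of 1.117, 1.401 and 1.24 against 24.53 for the next pair. One pair lay within day 22, one within day 10 and one within the xenograft cells titled day 7. The last crosses the runs A412U and A413U and the day 10 pair the runs A267T and A281U, so these runs need not be free of shared libraries. All 6 cells stayed in the sums, with 1 cell of each pair left out as an alternative chosen after the pairs were seen. Total counts per cell ranged from 181595 to 2536170. No label names a separate culture or animal for a cell, so cells were never used as replicates. What is called a run here was read from the prefix of the cell name in the title. Counts were summed per day and course, where a course is the pair of runs that share days, which gave 8 sums of culture cells for 7 days, and per titled day in xenografts, with each of the 3 xenograft runs also alone.

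The trend over time in culture was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, scaled by TMM factors and fitted with the quasi-likelihood method on log2 of the days after doxycycline withdrawal plus 1, with the course as a covariate and 5 residual degrees of freedom. This left 15262 genes, with a common biological coefficient of variation of 0.672. The fitted change is the slope times the 4 log2 units between day 7 and day 22, its standard error follows from the quasi-likelihood F, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fits to a single course, or without an end day, are scaled by the same 4 units, so their values reach beyond the days they cover. Gene lists were tested on the trend with camera of limma 3.58.1 at a preset correlation of 0.01, and with an estimated correlation beside it. The rotation test fry was also run. The change of FLI1 was read first, as a check of the labels. On simulated counts of 14722 genes, with 100 changed by 2 and 100 by 5 on the log2 scale, the fit called 3% of the former and 71% of the latter, and 4.13% of the unchanged genes had an unadjusted p under 0.05. With linear days and no course term (14543 genes) it called 25% and 93%, with 4.23%. The simulated counts held no difference between the courses and no correlation between genes. These rates therefore do not show how often the fit without a course term calls genes falsely where the courses differ.

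Xenografts have 1 sample per group, so no test was made. CPM values used TMM factors, log2 folds a prior count of 2, and list medians were set among 10000 random lists of the same size drawn from 9621 genes with a mean of at least 5 CPM in 20 bins of level. Poisson and binomial intervals are exact at 95%. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group. It covers the counting of reads only and not the sampling of cells. On simulated sums of 7065 genes, log2 folds of 1 and 3 came out at a median of 0.996 and 2.997. The culture trend, with its sign turned, and the xenograft folds were correlated across the genes with at least 5 CPM in both. For comparisons between cells, each cell was thinned to 50000 counts drawn at random, which left out 0 cells, and a list score is the mean of log2(CPM + 1) over the members. Thinning, scores and correlations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

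The 18 lists were EWSR1-FLI1-activated and EWSR1-FLI1-repressed targets, mesenchymal and matrix genes, actin and focal adhesion genes, G1/S genes, G2/M genes, hypoxia response, glycolysis, nuclear oxidative phosphorylation, ribosomal protein, mitochondrially encoded, cholesterol synthesis, endoplasmic reticulum stress, immediate early and heat shock, p53 target, interferon response and neural genes, and markers of blood and endothelium. Members were chosen from general knowledge of these pathways, not from these samples, but the target lists go back to work on Ewing lines that can include this one. By rule, the text names for the culture trend FLI1, EWSR1, the 10 genes with the largest rise and fall among those called with at least 20 CPM and 1 direction in both courses, of which there were 0, and up to 3 members of each list with the largest change among those with at least 20 CPM. For xenografts it names FLI1, EWSR1, the 10 highest and 10 lowest genes by fold among those with at least 50 CPM in the higher group, a count in at least 20% of its cells and 1 direction in all 3 runs, and up to 3 members per list with the largest fold among those with at least 20 CPM. Members of lists given as a count are left out in part. Some genes that the rule takes are not reported here.

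The alternatives for the trend were DESeq2 size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, at least 10 CPM in 4 sums, linear days, no course term with both day 11 sums merged, the first or the second run of each course alone, each sum left out, each course alone, cells thinned before summing, and cells of at least 200000 counts and 2000 genes. The last left in every culture cell, so for the trend it repeats the planned fit and is no separate alternative. Linear days with no course term, each day left out of that fit, and the estimated correlation counted as a separate result were added after the data were seen. For xenografts they were groups by description, each run alone or left out, prior counts of 0.5 and 10, library size alone, DESeq2 size factors, thinned cells and the stricter cell filter. Scores were also taken without thinning, at 200000 counts, with a pseudocount of 10 and within runs. The shift of the median gene between xenograft groups was -0.06 with TMM factors and -0.09 with library size alone, and it was -0.13 within A413U and 0.18 within A540U, so folds within those runs are read relative to these.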

Results

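Full-length RNA of single cells was sequenced from A673/TR/shEF, a Ewing sarcoma line that makes a short hairpin RNA against the fusion transcript EWSR1-FLI1 when doxycycline is given. In 383 cultured cells, the fusion was knocked down with doxycycline for 7 days, and cells were taken on day 7 and at 6 later times after the drug was withdrawn. The culture days were 7, 9, 10, 11, 14, 17 and 22, with 48 cells each except for 96 cells on day 11 and 47 on day 17. Days 7, 9, 10 and 11 came from the runs A267T and A281U, called course 1 here, and days 11, 14, 17 and 22 from the runs A295U and A296U, called course 2. A run here is the prefix of a cell's name in its title, so runs and courses are inferred units. Further cells came from tumours grown in immunodeficient mice. The runs A412U, A413U and A540U held 47, 48 and 11 cells titled day 0 and 43, 32 and 34 titled day 7. The total count per cell ranged from 181595 to 2536170 with a median near 1012900, and the summed count per culture day from 47579540 to 104808017. The xenograft sums held 144125313 counts for day 0 and 76176374 for day 7. A median of 8299 genes per cell was detected on culture day 22 and 7081.5 on day 7, against 5880.5 in xenograft cells titled day 0 and 3435 in those titled day 7. No label names separate cultures or animals, so p-values over the days measure only the spread between these sums, which may be technical. Each xenograft group counts as 1 sample with no replicate. Intervals given for counts cover the counting of reads only and leave out the spread between cells and between samples. Without molecular identifiers PCR copies cannot be told apart, so these intervals may be too narrow even for molecules. Intervals given for shares cover the sampling of cells within a group only.

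The first question was whether the hairpin's target followed the labels. FLI1 (ENSG00000151702), whose reads come from the fusion and from any unrearranged FLI1, had 30.1 CPM on day 7, 22.9 on day 9, 33.8 on day 10 and 38.8 on day 11 of course 1. In course 2 it had 32.9 CPM on day 11, 64.9 on day 14, 88.1 on day 17 and 62.02 on day 22. The fitted log2 change of FLI1 from day 7 to day 22 was 0.98 ± 0.74 (SE, 8 sums), which did not pass the test (adjusted p = 0.669, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). EWSR1 (ENSG00000182944), the 5' partner, had a fitted change of 0.83 ± 0.51 (adjusted p = 0.594 by the same edgeR test with Benjamini-Hochberg adjustment). In single cells thinned to 50000 counts, FLI1 was detected in 39.6% of the cells on day 7 (95% exact interval 25.8 to 54.7%) and in 83.3% on day 22 (69.8 to 92.5%). The unthinned shares were 58.3% and 95.8%. FLI1 differed between the runs on day 7, with 41.5 CPM in A267T and 15.8 in A281U, and over the runs A267T and A295U alone its fitted change was -0.05. Leaving out day 7 of course 1 gave a change of 2.81, leaving out day 11 of course 2 gave 0.37, and the runs A281U and A296U alone gave 2.58, with no call in any of these fits. In xenografts, FLI1 stood at 41.5 CPM (exact Poisson interval 40.04 to 42.96) in cells titled day 7 and 80.8 CPM (79.3 to 82.3) in cells titled day 0, a log2 difference of -0.96. It was -0.80 in A412U and -1.51 in A413U, but 0.12 in A540U, where the median gene was shifted by 0.18, so that run shows no clear difference in FLI1. Over all runs, FLI1 was detected at 50000 counts in 60.4% of the cells titled day 0 and 19.3% of those titled day 7. The unthinned shares were 75.5% and 29.4%, and fewer genes were detected per cell in the latter group.

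**Figure D1:**
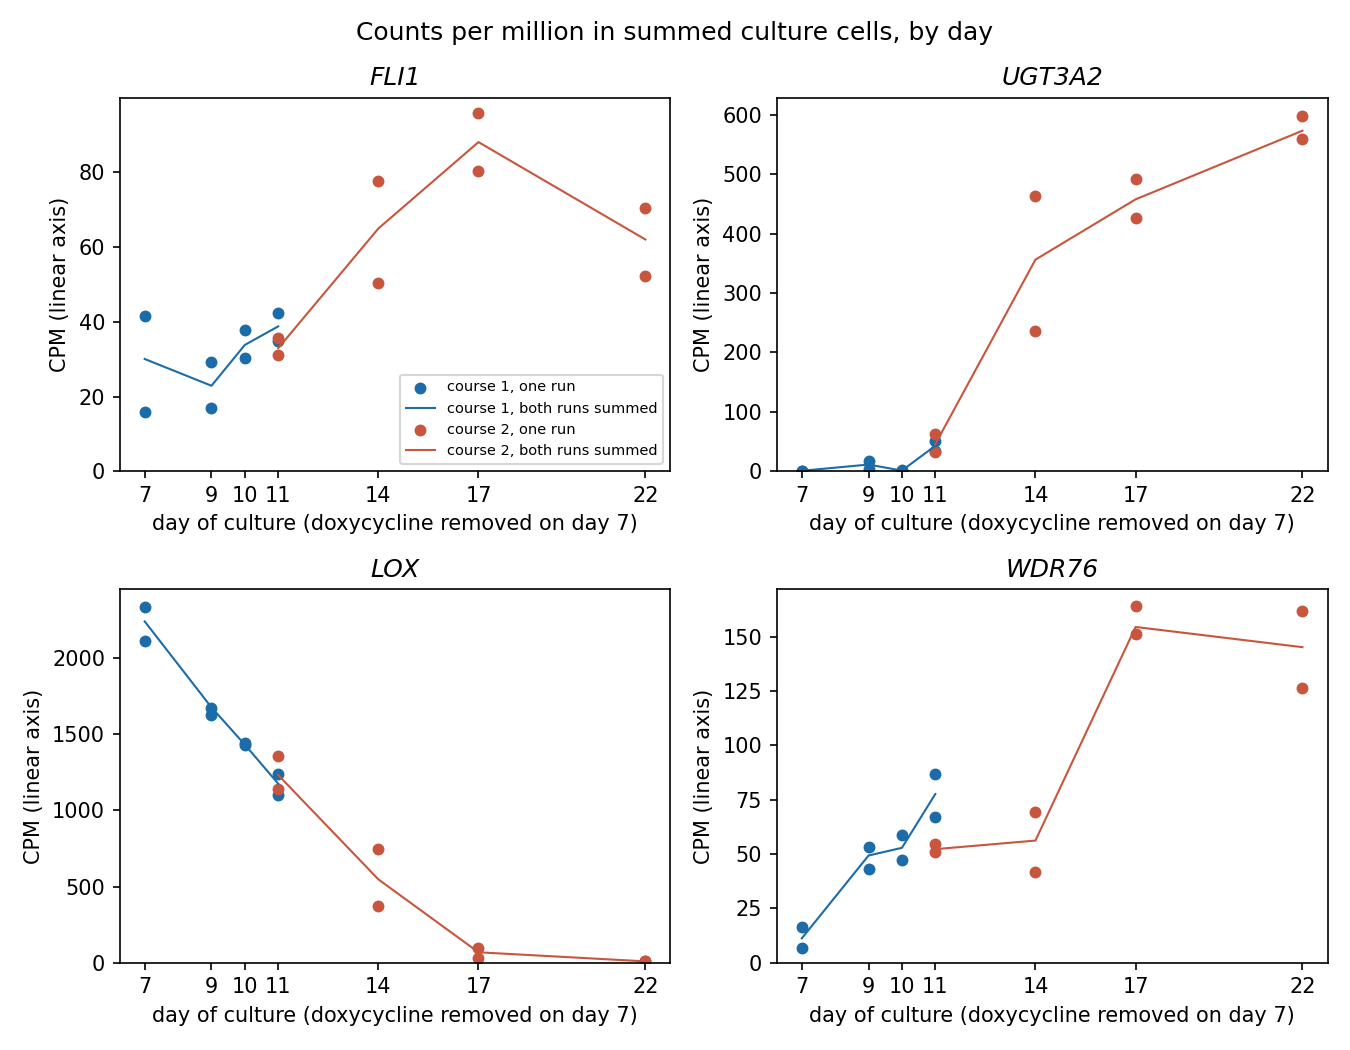
CPM of FLI1, UGT3A2, LOX and WDR76 (y axes, linear) against the day of culture (x axes), with points for single runs and lines for both runs of a course summed. UGT3A2 goes from 0.92 CPM on day 7 to 573 on day 22, and LOX from 2243 to 7.98.

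Targets that the fusion activates rose after doxycycline was withdrawn, and targets that it represses fell. The activated list had a median fitted log2 change of 2.21 between day 7 and day 22, with 21 of its 24 measured members above 0 and 3 below. UGT3A2, a sugar transferase gene, went from 0.92 CPM on day 7 to 573 on day 22 (fitted change 8.41 ± 2.30 SE) and LIPI, a phospholipase gene, from 14.1 to 474.3 (5.23 ± 1.83). STEAP1, a membrane metalloreductase gene, went from 29 CPM on day 7 to 68.9 on day 14 and 188.4 on day 17 (3.19 ± 0.98). The repressed list had a median of -2.66, with 16 of 18 members below 0. LOX, the collagen cross-linking enzyme, went from 2243 CPM on day 7 to 7.98 on day 22 (-6.52 ± 3.11), and CTGF, a matrix-associated growth factor, from 1106 to 13.4 (-6.31 ± 2.33). The move was late. The median log2 difference of the activated members was 0.20 from day 7 to day 11 in course 1, 0.95 from day 11 to day 14 in course 2 and 0.90 from day 14 to day 22, while the courses differed by 0.11 on day 11. Both lists passed camera with a preset correlation, at an adjusted p = 7.4e-08 for the activated and 2.2e-08 for the repressed targets. Neither did otherwise, with an adjusted p = 0.244 with an estimated correlation for the activated and an adjusted p = 0.216 with an estimated correlation for the repressed targets. On log time no member passed edgeR's test over all genes, and 3 activated members were higher and 1 repressed member lower when adjusted over the list alone. In course 1 alone the activated list gave 1.03 and lost its call (adjusted p = 0.288), and the repressed list gave -0.74, against 5.81 and -10.11 in course 2 alone. These values scale the slope of a single course to the whole span from day 7 to day 22. They are extrapolations and not changes seen within a course, where the activated members moved by the steps given above. Without day 7 of course 1 the activated list gave 6.30 and the repressed list -6.12, and without day 22 the repressed list gave -1.17. The median share of counts on the nuclear RNA MALAT1, the stand-in for RNA quality, changed too, with 2.79% on day 7, 1.16% on day 9, 1.47% on day 10, 1.29% on day 11, 1.77% on day 14, 0.708% on day 17 and 0.908% on day 22. No test here separates RNA quality from the changes of the lists in culture.

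Genes of the extracellular matrix and of the actin cytoskeleton fell over the same days. The mesenchymal and matrix list had a median fitted log2 change of -3.10 with 21 of 23 members below 0, and the actin and focal adhesion list -1.70 with 16 of 17. COL6A3, a collagen VI chain, went from 769 CPM on day 7 to 30.4 on day 22 (-4.94 ± 1.22 SE) and THBS1, an adhesive glycoprotein of the matrix, from 284.7 to 1.03 (-9.31 ± 3.86). TGFBI, a matrix adhesion protein induced by TGF-beta, had a fitted change of -5.60 ± 3.26, but 0.18 in course 1 alone. Among actin genes, TPM1, a tropomyosin, went from 703 to 21.9 CPM (-4.11 ± 1.75), AMOTL2, a junction protein, from 67.6 to 7.11, and ANKRD1, a muscle and fibroblast stress gene, from 169.2 to 0. The camera adjusted p was 6.0e-12 for the matrix list and 2.4e-07 for the actin list, against an adjusted p = 0.216 with an estimated correlation and an adjusted p = 0.244 with an estimated correlation. On linear days both held, with adjusted p = 0.0223 and adjusted p = 0.0325 with an estimated correlation, and so did the repressed targets with 0.0317. The activated targets (adjusted p = 0.0637 with an estimated correlation) and the G1/S and G2/M genes (adjusted p = 0.441 with an estimated correlation for each) did not hold on linear days. On log time no member passed over all genes, and 8 matrix and 2 actin members were lower when adjusted over the list alone. In course 1 alone the actin list lost its call (-0.49, adjusted p = 0.0839) and the matrix list gave -1.27, against -4.002 and -7.86 in course 2 alone. These values too are slopes of a single course extrapolated to the span from day 7 to day 22. Leaving out day 7 of course 1 gave -5.85 for the matrix and -3.35 for the actin list, and leaving out day 22 gave -1.66 and -0.98.

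Cell-cycle genes had upward fitted trends after withdrawal, but did not rise steadily. The median G2/M score per cell was 1.56 on day 7, 4.10 on day 9, 2.46 on day 10, 3.86 on day 11, 2.41 on day 14, 6.81 on day 17 and 7.55 on day 22. The median G1/S score was 1.50 on day 7, 4.07 on day 11, 2.82 on day 14 and 5.61 on day 22. All 42 measured G1/S genes had a fitted change above 0 (median 2.42), as did 52 of 53 G2/M genes (median 2.67). EXO1, a DNA repair exonuclease, went from 0.42 CPM on day 7 to 57.9 on day 22, and CDC45, a subunit of the replicative helicase, from 4.39 to 138.9 (4.66 ± 1.37 SE). WDR76, a WD-repeat gene, went from 11.1 to 145.1 CPM (4.57 ± 0.69). BIRC5, the mitotic survivin gene, went from 26.4 to 434 CPM (4.75 ± 1.20), with fitted changes of 3.87 for BUB1, a spindle checkpoint kinase, and 3.75 for DLGAP5, a spindle protein. The camera adjusted p was 4.6e-29 for G1/S and 4.0e-27 for G2/M genes. The estimated correlation ended both calls, with an adjusted p = 0.189 and an adjusted p = 0.217 with an estimated correlation. No member passed edgeR's test over all genes, and 23 G1/S and 11 G2/M genes were higher when adjusted over the list alone. Without day 7 of course 1 the G2/M median was 1.73.

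Of the stress lists, endoplasmic reticulum stress genes had a fitted fall, with a median log2 change of -2.11 and 14 of 14 members below 0. With no course term 10 of 14 were below 0 and 4 above, and on linear days 8 below and 6 above. The fitted fall is not a plain difference between the end days. The members ASNS, ATF4, CHAC1, DDIT3, SESN2 and TRIB3, chosen after their values were seen, had a mean log2(CPM + 1) of 7.59 on day 7 and 7.66 on day 22. HSPA5, the chaperone BiP, went from 3715 CPM on day 7 to 737 on day 22 (-3.001 ± 0.54 SE) and DNAJB9, its cochaperone, from 331 to 36.9 (-3.35 ± 0.61). ASNS, asparagine synthetase, had 862 CPM on day 7, 130 on day 11 of course 1 and 925 on day 22. Hypoxia response genes also fell (median -1.59, 17 of 18 below 0). ADM, adrenomedullin, went from 90.1 to 2.04 CPM, VEGFA, the vascular growth factor, from 70.1 to 24.5 and SLC2A1, a glucose transporter, from 34.3 to 14.4. Falls were also fitted for p53 target genes (-1.73, 8 of 9 below 0), ribosomal protein genes (-0.59, 28 of 29) and interferon response genes (-0.73, 12 of 15). In that order the camera adjusted p was 1.4e-08, 1.8e-07, 0.00745, 0.00124 and 0.0497, and with an estimated correlation the adjusted p = 0.189, 0.216, 0.189, 0.589 and 0.314. Adjusted over the list alone, 5 endoplasmic reticulum stress genes were lower, no hypoxia, p53 or ribosomal gene passed, and 3 interferon genes were lower and 1 higher, with 0 over all genes. Without day 7 of course 1 the endoplasmic reticulum list gave 0.34 (adjusted p = 0.924) and the p53, ribosomal and interferon lists lost their calls (adjusted p = 0.609, 0.268 and 0.609), the last also without day 10, day 11 of course 1 or day 22 (adjusted p = 0.0623, 0.172 and 0.196). On linear days these lists lost their calls as well (adjusted p = 0.0814 for the endoplasmic reticulum, 0.188 for p53, 0.0814 for ribosomal and 0.330 for interferon genes), and course 2 alone gave 0.15 for the endoplasmic reticulum and 0.04 for the p53 list. The fit to course 2 alone also ended the calls of the ribosomal (adjusted p = 0.672) and interferon genes (adjusted p = 0.766). The p53 and interferon calls were lost as well at 10 CPM or more in 4 sums (adjusted p = 0.0504 and 0.172) and with no course term (adjusted p = 0.0714 and 0.0533). The interferon call was also lost with thinned cells (adjusted p = 0.0989) and with either single run of each course (adjusted p = 0.0981 and 0.864). Without day 11 of course 2 the median of the interferon response genes was -1.72 (adjusted p = 0.00517).

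No trend was called for cholesterol synthesis genes (median 0.09, mean -0.04, adjusted p = 0.941), glycolysis genes (0.39, adjusted p = 0.385) or nuclear oxidative phosphorylation genes (0.08, adjusted p = 0.653). Immediate early and heat shock genes were not called either (-0.84, adjusted p = 0.296), with 2 members lower when adjusted over the list alone. The camera adjusted p with an estimated correlation was 0.963, 0.791, 0.963 and 0.678 for these lists. Neural genes had a median of -0.61 over 7 members although the test pointed up (adjusted p = 0.941). The 5 measured markers of blood and endothelium had a median of 1.03 although the mean was -3.09 and the test pointed down (adjusted p = 0.462). Those markers summed to 3.37 CPM on day 7 and 3.25 CPM on day 22. Leaving out day 7 of course 1 gave calls downward for cholesterol synthesis (-1.73, adjusted p = 0.00744) and oxidative phosphorylation genes (-0.92, adjusted p = 0.00310). Leaving out day 11 of course 2 gave calls upward for cholesterol synthesis (1.05, adjusted p = 0.0230), glycolysis (1.07, adjusted p = 0.0441) and oxidative phosphorylation genes (0.61, adjusted p = 0.0230). Of the 11 lists called by camera, the rotation test fry kept p53 target genes alone (adjusted p = 0.0332). It gave G1/S and endoplasmic reticulum stress genes an adjusted p = 0.0862, and activated targets, repressed targets and matrix genes an adjusted p = 0.150. On linear days fry gave an adjusted p = 0.0119 for activated targets and 0.00570 for repressed targets, matrix genes and actin genes, and lost the p53 target genes (adjusted p = 0.207).

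Across all genes, LOX, THBS1 and TPM1 were lower when time was taken as linear days (adjusted p = 0.0209, 0.0105 and 0.0209 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment). On log time without a term for the course, STEAP1 was higher and COL6A3, DNAJB9 and HSPA5 were lower (adjusted p = 0.0371, 0.0339, 0.0158 and 0.0158 by the same test), and UGT3A2 (0.0275) and WDR76 (0.0174) were higher. With log time and the course term, as fixed before the data were examined, 0 of 15262 genes passed edgeR's quasi-likelihood test. An unadjusted p under 0.05 was found for 1650 genes where 763 are expected without any trend, and DESeq2's Wald test called 547 genes, 351 of them higher. Linear days called 0.734% of 15262 genes with 7 of them higher. Log time without the course term called 539 of 15131 genes with 357 of them higher, and both changes together 971 with 388 higher and 583 lower. These 971 held 96.4% of the genes called on linear days and 350 of the 539. Without day 7 of course 1 the count of 0 became 2.

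The second question was how fusion targets differed between tumours titled day 7 and day 0 of doxycycline. Title and sample description give opposite drug states for all cells of the runs A412U and A413U and the same state for the 45 cells of A540U. Groups here follow the titles, which the deposited table's own group names match in all 598 cells. In cells titled day 7, MGP, a matrix calcification inhibitor, had 2978 CPM against 3.44 in cells titled day 0, and VCAN, the proteoglycan versican, 795 against 1.2. PDGFRA, a growth factor receptor of mesenchymal cells, had 139.5 CPM against 0.73, PLAT, tissue plasminogen activator, 182.4 against 0.67, and DKK1, a Wnt antagonist, 192.1 against 0.34. PRL, the hormone prolactin, was at least 4264-fold higher and the long non-coding RNA RP11-544L8__B.4 at least 3767-fold higher, against a floor of 3 counts over the cells titled day 0. IGFBP3, an IGF-binding protein that the fusion represses, had 148.9 CPM against 3 counts, a ratio of 7233 (counting interval 2475 to 35080). It was found in 38.5% of the cells titled day 7 and 0.943% of those titled day 0. PRICKLE2, a planar polarity gene, and SCARA3, a scavenger receptor, were higher too, with log2 folds of 10.71 and 8.35.

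At the other end, MBD3L3, a germline-type gene of a near-identical family whose reads are uncertain, was at least 1392-fold lower in cells titled day 7. E2F2, a cell-cycle transcription factor, had 0.29 CPM against 73.7, PRSS35, a protease-like gene, 0.52 against 213, and MYEOV 0.88 against 137.3. Lower as well were KMO, a tryptophan-pathway enzyme (log2 fold -7.24), TTC27 (-6.26), TRAV1-2, a T cell receptor gene segment (-6.20), and MMP1, interstitial collagenase, with 8.38 against 481.5 CPM. Genes were ranked by title among those with 1 direction in all 3 runs, so their direction within a run is no separate check. Some were far closer to 0 in A540U, with log2 folds of -0.63 for MMP1, -1.01 for KMO and -2.27 for MBD3L3, which had 0 against 0.45 CPM there, and 2.95 for PLAT, with 68.7 against 8.77 CPM. The folds of TRAV1-2 and DKK1 depend on 1 run each, with log2 folds of -4.85, -10.98 and -9.42 for TRAV1-2 in A412U, A413U and A540U and 12.96, 6.0 and 9.93 for DKK1. Leaving out A412U gave -11.46 for TRAV1-2, and leaving out A413U gave 12.59 for DKK1.

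By list, activated targets were lower in cells titled day 7, with a median log2 fold of -2.46 and 21 of 21 members below 0. Repressed targets (median 2.54, 14 of 15 above 0) and mesenchymal and matrix genes (3.63, 20 of 21 above 0) were higher. Among activated targets, UGT3A2 had 24.3 against 1006 CPM, PRKCB, a protein kinase C, 18.5 against 375, and LOXHD1 5.17 against 84.7. NT5E, the CD73 ectoenzyme among repressed targets, had 148.9 against 1.60 CPM. Among matrix genes, COL6A3 had 872 against 6.59 CPM, POSTN, periostin, 411 against 3.99, and COL1A1, a collagen I chain, 540 against 8.50. Of 10000 random lists of the same size and mean level, 0% lay below the activated median, and 100% below both others. Per run, in the order A412U, A413U and A540U, the medians were -2.47, -2.39 and -3.03 for activated targets, 2.60, 3.79 and 4.11 for repressed targets and 3.05, 2.77 and 5.04 for matrix genes. THBS1 had 0 counts in cells titled day 0, so it was at least 690-fold higher in cells titled day 7, and with it at that bound the matrix median was 3.63 as well. Its log2 fold was 6.73, 1.04 and 8.49 in A412U, A413U and A540U, so it differed little in A413U.

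Proliferation and metabolic genes were lower in cells titled day 7. The median log2 fold was -2.09 for G1/S genes (41 of 42 below 0), -1.97 for G2/M genes (52 of 53), -2.13 for glycolysis genes (16 of 16) and -1.66 for cholesterol synthesis genes (14 of 14). In A412U, A413U and A540U the G2/M median was -1.12, -2.76 and -1.70, and -2.84 with A412U left out. Over all runs the median was -0.86 for ribosomal protein genes (29 of 29) and -0.62 for oxidative phosphorylation genes (22 of 26). CDC45 had 4.13 against 83.2 CPM, NDC80, a kinetochore gene, 8.06 against 180, and HK2, a hexokinase, 11.7 against 82.7. DHCR7, the enzyme that makes cholesterol from its precursor, had 1.94 against 58.1 CPM, and RPL4, a large-subunit protein, 839 against 2630. The medians of these 6 lists over all runs lay at the 0, 0, 0, 0.01, 0.54 and 3.48 percentiles of random lists, against a median of -0.06 over 9621 genes. Immediate early and heat shock genes were higher (1.17, percentile 99.7), with 826 against 75.4 CPM for FOSB, a transcription factor induced within minutes of a stimulus, and 46.9 against 2.24 for IER3. Interferon response genes had a median of 0.95 (percentile 95.5) and neural genes 2.37 over 5 members (99.8). Both differed by run, in the order A412U, A413U and A540U, with 1.23, 0.88 and 4.67 for interferon and 0.93, -0.41 and 6.44 for neural genes. Hypoxia (0.19), endoplasmic reticulum stress (0.14), actin (0.07) and p53 target genes (0.34) lay between the percentiles 65 and 73.2. In the same order of runs, hypoxia genes had 0.18, 0.31 and -0.28, with 0.88 when A412U was left out, and p53 target genes -0.054, -0.24 and 2.16. Actin genes had 0.44, 0.54 and 0.45 within the runs, each above the 0.07 of the pooled sums. Ribosomal protein genes had -0.51, -0.82 and -0.67, each above their pooled -0.86. Cells titled day 7 also had a median of 3.22% of their counts on the nuclear RNA MALAT1 against 0.766%. Blood and endothelial markers summed to 36.7 against 7.32 CPM, of which the receptor gene KDR held 34.7, and 1 of the 13 markers was high enough for a list value, so none is given.

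**Figure D2:**
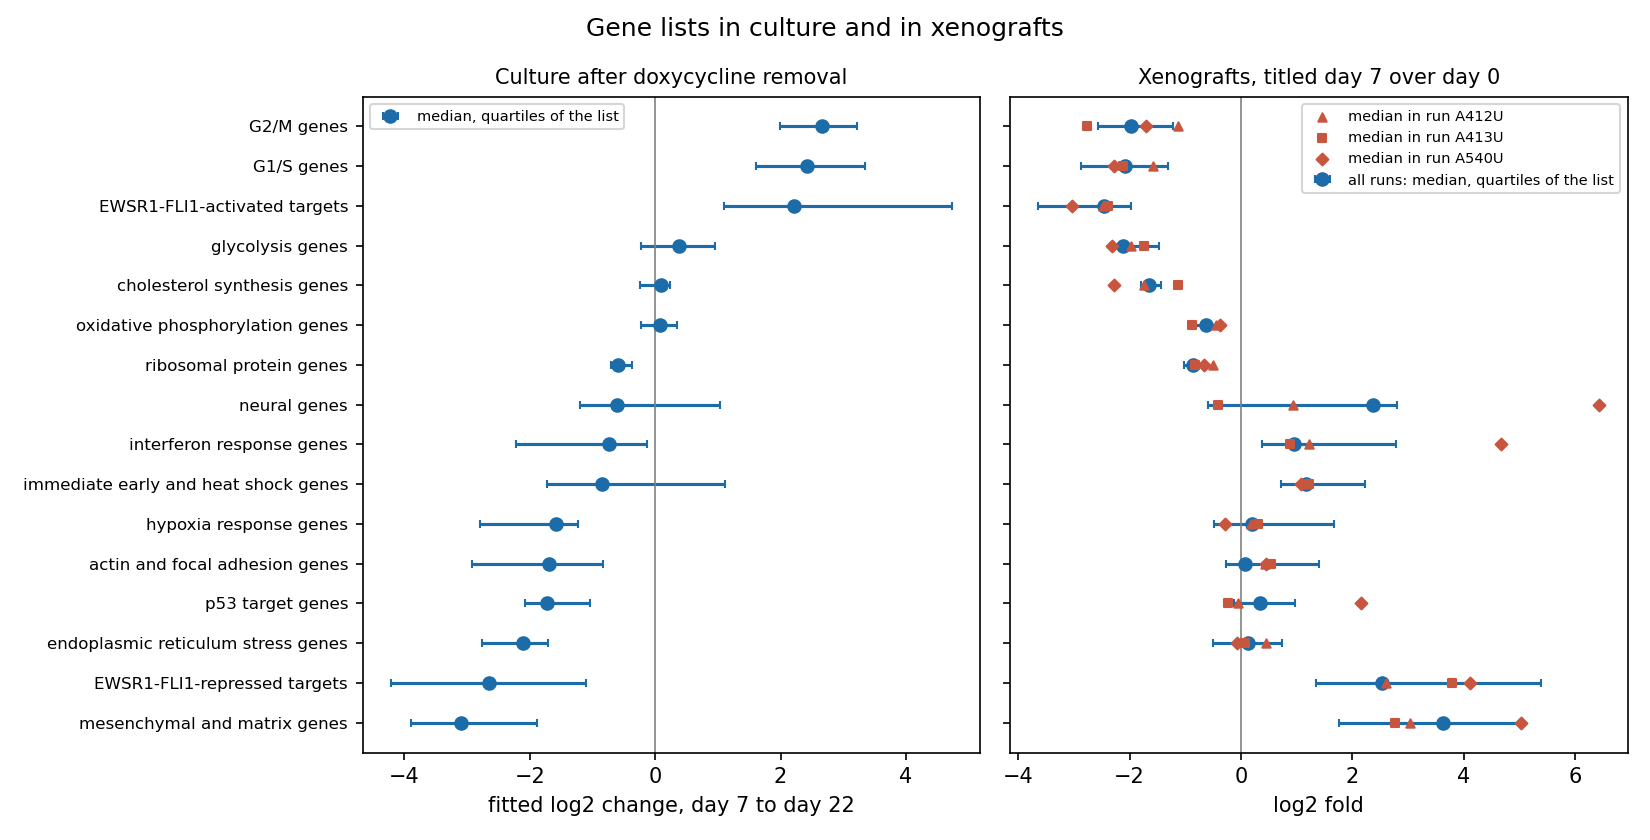
Median log2 change of each gene list with quartiles over its members, fitted from day 7 to day 22 in culture (left) and between xenograft cells titled day 7 and day 0 (right), with each run's median as a small mark. Activated targets sit at 2.21 in culture and -2.46 in xenografts, and matrix genes at -3.10 and 3.63.

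Set against each other across genes, the knock-down side of the culture course and the xenograft folds had a Pearson correlation of 0.413 and a Spearman correlation of 0.354 over 8740 genes, and 61.1% of the genes had the same sign. Genes are not independent replicates, and no library is shared by the comparisons. UGT3A2 and LIPI were lower, and COL6A3 and IGFBP3 higher, on the knock-down side of both systems and in every xenograft run. SCARA3, DKK1 and PRICKLE2, higher in every xenograft run, had fitted changes of -1.38, -1.43 and -0.36 on the knock-down side of culture, with opposite signs in the courses. Within the runs A412U, A413U and A540U the Pearson correlation was 0.322, 0.320 and 0.319. With the groups taken from the descriptions it was -0.252, and without a filter on level 0.186.

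The last question, posed by the series itself, was how cells of a group differ from each other. The activated-target score, the mean log2(CPM + 1) of the list at 50000 counts per cell, had a median of 1.73 on day 7, 2.33 on day 11, 3.38 on day 14, 4.38 on day 17 and 4.91 on day 22. It was 4.91 and 1.25 in xenograft cells titled day 0 and day 7. A score at fixed depth also falls where fewer genes are detected, and cells titled day 7 had a median of 2275 genes against 4042.5. Their hypoxia score was 1.66 against 2.70, although the median log2 fold of that list between sums was 0.19. The score of 1.25 is thus no measure of target activity alone, and shares of cells with a count have the same limit. The SD of the activated score across the cells of a day was 0.42 on day 7, 0.93 on day 14 and 0.55 on day 22, and within the runs of day 14 it was 0.91 in A295U and 0.84 in A296U. On day 14, cells with a higher activated score had lower scores of repressed targets (Spearman rho -0.676, and -0.821 and -0.520 within the runs) and of mesenchymal and matrix genes (-0.616). Day 14 was the extreme for the repressed targets. On days 7, 9, 10, 11, 17 and 22 that rho was 0.054, -0.093, -0.112, -0.111, -0.379 and -0.207. In xenograft cells titled day 0 and day 7 it was 0.149 and 0.014. The activated score went with the G2/M score on day 7 (rho 0.352), day 10 (0.415), day 11 (0.543, between 0.320 and 0.663 within the 4 runs) and day 14 (0.412). The relation was weaker on day 9 (0.162) and was not seen on day 17 (-0.105) or day 22 (-0.204). Its rho was 0.076 and 0.318 in xenograft cells titled day 0 and day 7. At 50000 counts, MKI67, the proliferation antigen, was detected in 8.33% of the cells on day 7 (exact interval 2.32 to 19.98%) and 93.8% on day 22 (82.8 to 98.7%), and in 22.9% and 100% unthinned. In xenograft cells titled day 0 and day 7 it was detected in 87.7% (79.9 to 93.3%) and 11.9% (6.51 to 19.5%), and in 97.2% and 26.6% unthinned. At that depth, a count of the blood gene PTPRC was found in 0% of the cells titled day 0 and in 0.917% of those titled day 7. The 0% allows up to 2.83% of cells with a count by a floor of 3 cells, and up to 3.42% by the exact interval. These relations across cells have no p-value, because cells are not replicates.

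**Figure D3:**
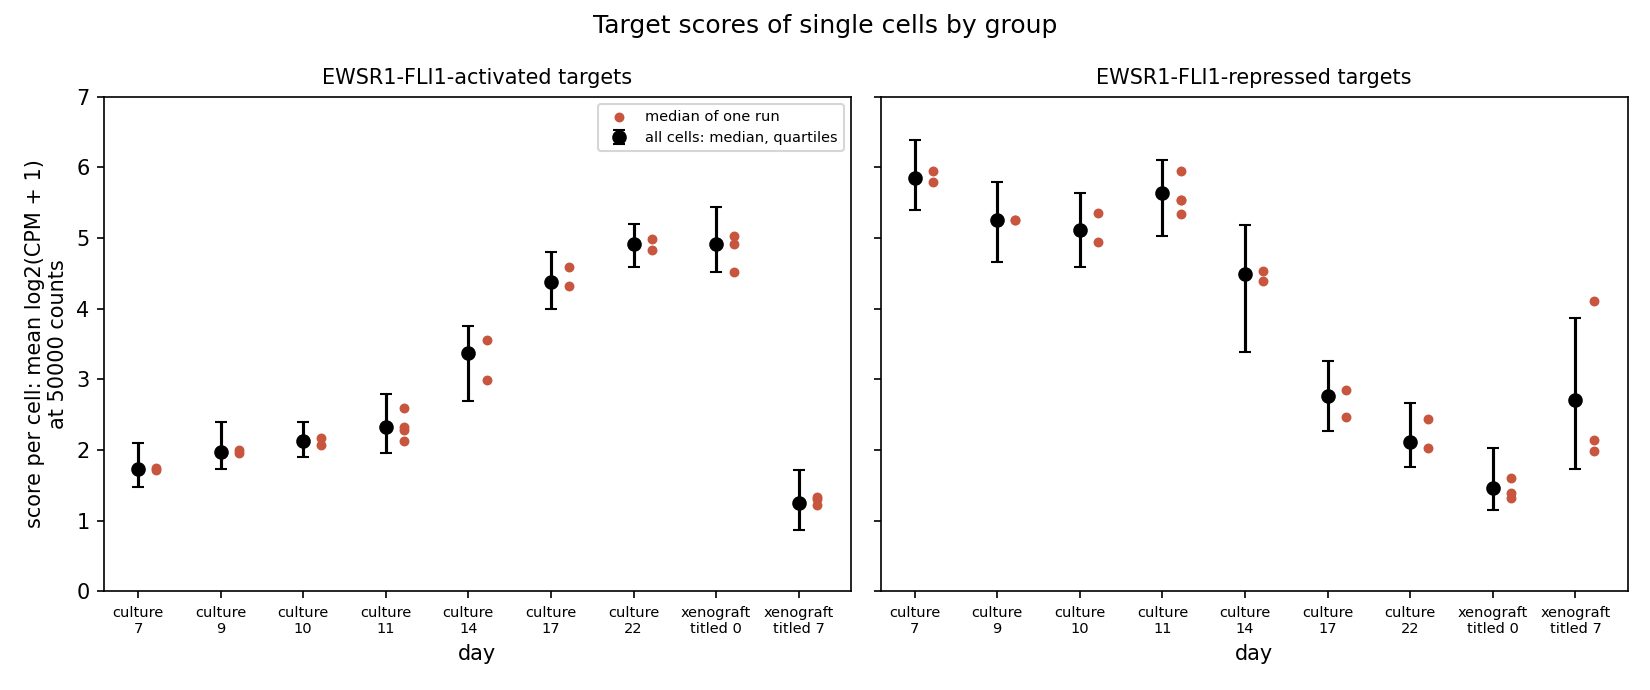
Scores of activated (left) and repressed targets (right) per cell, as the mean log2(CPM + 1) at 50000 counts, with the median and quartiles of each group in black and run medians in red. The activated score goes from 1.73 on culture day 7 to 4.91 on day 22, and is 1.25 in xenograft cells titled day 7. Fewer genes were detected in the latter, which also lowers a score.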

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

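No test was made in this part, and the comparison of directions between the systems was chosen only after the values were seen. Of 61 genes and lists, 2 had one direction on the knock-down side of the culture course in both courses and the opposite one in all 3 xenograft runs. Ribosomal protein genes were higher on the knock-down side in culture, with a median log2 change of 0.59 (0.67 in course 1 and 0.54 in course 2), and lower in xenograft cells titled day 7, with medians of -0.51, -0.82 and -0.67 in A412U, A413U and A540U, a gap of -1.46 between the systems that was not tested. SLC2A1, a glucose transporter, had a fitted change of 2.27 on the knock-down side in culture (0.54 in course 1 and 5.09 in course 2) and xenograft log2 folds of -2.99, -4.53 and -2.95 in these runs, a gap of -5.43 that was not tested either. The values of single courses are extrapolated to the whole span of days, so only their direction is used here.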

How the results depend on the processing

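The tests chosen only after the result was seen were linear days with no course term, each day left out of that fit, 1 cell of each near-identical pair left out, the estimated correlation, and the culture against xenograft correlation within A412U and within A413U. No paired analysis was possible because no label gives a replicate number that culture days or xenograft groups share, so courses and runs stand in its place. The cause of each change below was not tested. In the planned fit, simulated log2 changes of 2 were called in 3% of genes and changes of 5 in 71%, so changes near 2 would mostly be missed, and xenografts have 1 sample per group. The filter on cells removed 0 cells, so the alternative without it has no value.

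The percent of tested genes called by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 0 as planned, was 0.00486 without a low-count filter (1 gene), 0.734 on linear days, 3.56 with no course term, 0.0778 in course 2 alone, and 6.42 on linear days with no course term. DESeq2's Wald test called 3.58. Leaving out each sum gave 0 to 0.0132, the latter being 2 genes without day 7 of course 1. On linear days with no course term it was 5.45 without day 7, 2.99 without day 9, 3.18 without day 10, 2.98 without day 11, 7.32 without day 14, 1.98 without day 17 and 1.30 without day 22.

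Of 17 lists in culture, 11 were called as planned, 7 on linear days, 7 in course 2 alone and 0 with an estimated correlation, where the medians stay at 2.21 for activated and -2.66 for repressed targets. Of 372 values of lists under alternatives, 297 kept their direction and their side of the threshold, 36 lost a call, 5 gained one and 34 changed direction. Of 528 values of named genes, 36 gained a call, 6 changed direction and the others kept both. Both totals include the stricter cell filter, which left in every culture cell, so its values equal the planned ones by construction. Without a low-count filter the neural median was 1.05, and at 10 CPM or more in 4 sums it was 0.52. On linear days the medians that changed direction were -0.45 for cholesterol synthesis, -0.070 for glycolysis, -4.52 for blood and endothelial markers and -0.22 for oxidative phosphorylation, with 0.45 for ASNS. With no course term they were -0.80, -0.0035, -5.41 and -0.28, with 0.018 for ASNS. With both changes they were -1.02, -0.10, -6.51 and -0.38, with 0.82 for ASNS. Cholesterol synthesis was then called downward, at an adjusted p = 0.0330 with no course term and 0.0141 with both changes, but not with an estimated correlation (adjusted p = 0.673 and 0.544). In the runs A267T and A295U alone, FLI1 had -0.049 and cholesterol synthesis -0.29. In course 1 alone, activated targets had 1.03 without a call, TGFBI 0.18, immediate early genes 0.77 and neural genes 1.17, and blood and endothelial markers (5.87) and oxidative phosphorylation genes (0.60) gained a call. In course 2 alone, cholesterol synthesis had -1.25, glycolysis -0.38, endoplasmic reticulum stress 0.15, blood and endothelial markers -7.01, oxidative phosphorylation -0.85, p53 targets 0.035 and ASNS 4.52. The values of single courses are slopes extrapolated to the whole span of days. With 1 sum left out at a time, cholesterol synthesis ranged from -1.73 to 1.05, endoplasmic reticulum stress from -2.92 to 0.34, glycolysis from -0.55 to 1.07, immediate early genes from -2.33 to 0.33, blood and endothelial markers from -6.19 to 2.66, neural genes from -0.64 to 1.01, oxidative phosphorylation from -0.92 to 0.61, and the trend of ASNS in culture from -5.03 to 4.26.

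In xenografts, each list with 1 direction in all 3 runs turned when grouped by description. Grouped so, the median log2 fold was 1.28 for activated and -0.61 for repressed targets, 1.10 for G1/S, 1.27 for G2/M, -0.012 for actin, 0.62 for cholesterol synthesis, 1.11 for glycolysis, -0.40 for immediate early, -0.40 for interferon, -0.69 for matrix, 0.40 for oxidative phosphorylation and 0.47 for ribosomal protein genes, and 0 of the 20 genes ranked by title kept their direction, which follows in large part from how they were chosen. Activated targets had -3.03 in A540U alone, and repressed targets 3.79 in A413U and 4.11 in A540U. With 1 run left out, repressed targets ranged from 2.31 to 3.45 and actin genes from -0.090 to 0.84. Under the other alternatives, no list with 1 direction in all runs changed direction except actin genes. The culture against xenograft correlation was 0.186 without a filter on level, 0.530 at 50 CPM or more, -0.252 by description, and 0.322, 0.320 and 0.319 within A412U, A413U and A540U. Across cells, the relation of the activated score with the G2/M score on day 11 and with the repressed score on day 14 kept its sign without thinning, at 200000 counts, with a pseudocount of 10 and within runs.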

Other observations

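Tests chosen only after the result was seen are those of depth and of the culture knock-down behind genes per cell, the 3 tests of exchanged labels, the correlation of the amino acid and cholesterol groups over days, and the 3 sets of orderings of days.

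Fusion targets differed in the share of cells with a count. Shares in xenograft cells titled day 7 may also be lower because fewer genes were detected in them. At 50000 counts, LIPI was found in 14.6% of the cells on day 7 (25% unthinned), 58.3% on day 11, 79.2% on day 14 and 95.8% on day 22 (all cells unthinned), and in 97.2% and 43.1% of the xenograft cells titled day 0 and day 7. NR0B1, an orphan nuclear receptor gene that the fusion activates, was found in fewer cells, with 10.4% on day 7 (exact interval 3.47 to 22.7%) and 35.4% on day 22 (22.2 to 50.5%), and 18.75% and 60.4% unthinned. In xenografts it stood at 23.6% and 2.75%, and 42.5% and 5.50% unthinned. PAX7, a muscle stem cell transcription factor bound by the fusion, was found in 0% on day 7, which allows up to 6.25% of cells with a count by a floor of 3 cells and up to 7.40% by the exact interval, in 6.25% on day 22 (16.7% unthinned) and in 10.4% and 1.83% of the xenograft cells titled day 0 and day 7, but in 24.5% and 18.35% unthinned. CD44, a hyaluronan receptor that the fusion represses, was found in all cells on day 7, in 60.4% on day 22 (87.5% unthinned), and in 10.4% and 33.03% of the xenograft cells titled day 0 and day 7 (21.7% and 45.9% unthinned).

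The scores of other lists did not all follow the days in 1 direction. The G2/M score had a median of 1.56 on day 7, 4.10 on day 9, 2.46 on day 10, 3.86 on day 11, 2.41 on day 14, 6.81 on day 17 and 7.55 on day 22, and MKI67 was found in 68.8% of the cells on day 9 and 41.7% on day 14 (85.4% and 60.4% unthinned). The repressed score went from 5.85 on day 7 to 2.11 on day 22 and was 1.46 and 2.70 in xenograft cells titled day 0 and day 7, and the matrix score was 7.08, 3.45, 2.58 and 4.57 in the same order. The glycolysis score was 6.12 and 6.75 on culture days 7 and 22, and 6.75 and 3.30 in xenograft cells titled day 0 and day 7. These are values of 1 sample per group with no test. Scores in xenograft cells titled day 7 may also be lower because fewer genes were detected in them.

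Xenograft cells titled day 7 had fewer genes per cell, by a ratio of medians of 0.584 to cells titled day 0 with all counts. Lower depth and a few dominant genes are argued against, since the ratio was 0.563 at 50000 counts in every cell (0.518, 0.608 and 0.719 in A412U, A413U and A540U) and 0.564 with the 50 highest genes of each cell left out (0.521, 0.615 and 0.726). Mouse cells stay open, since 86.2% of the cells titled day 7 had a count of 22 zinc finger genes of a primate cluster (83.7%, 90.6% and 85.3% per run), below the 90% set beforehand, although culture day 7, with no mouse, had 87.5%, and these genes summed to 353.9 against 219.1 CPM in cells titled day 0, although in A540U, with 101.8 CPM titled day 7, the order was the other way. The knock-down itself may take part, since genes per cell at 50000 counts on culture day 7 were 0.866 of those on day 22 (0.856 to 0.887 between pairs of runs), though that drop is smaller than the one in xenografts. Day 7 and day 22 are of different courses. Day 14, 7 days after withdrawal, also had fewer genes (median 5120) than day 9 (5421.5), day 11 (5524) or day 22 (5717), so a drop is not particular to the drug. Animals and RNA quality were not tested.

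Title and description give opposite drug states in A412U and A413U. Exchanged titles are argued against, since the activated targets by title had a median log2 fold of -2.39 in the nearer of these runs and -3.03 in A540U, where both labels give the same state. Exchanged descriptions are consistent with the folds by title, which correlated with those of A540U at 0.3035 in A412U and 0.318 in A413U across 9621 genes. Exchanged titles in all 3 runs are argued against by the culture cells, whose knock-down side correlated with the folds by title at 0.322, 0.320 and 0.3188 in A412U, A413U and A540U. FLI1 itself had a log2 fold of 0.12 in A540U, near the 0.18 of that run's median gene, so the hairpin's target does not bear out that run's titles. That fold rests on 11 cells titled day 0 and 34 titled day 7.

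Matrix genes in cells titled day 7 might in part come from mouse fibroblasts whose reads align to human genes. Over cells with at least 2 of the primate zinc finger genes (67 titled day 7 and 94 titled day 0), the median log2 fold of the matrix genes was 3.08, 0.855 of the 3.60 over all cells scaled alike. Per run the ratio was 1.066, 0.877 and 0.798 in A412U, A413U and A540U, just under the bound of 0.8 in the last. That bound had to hold in every run, so the explanation stays open. The matrix list was also higher on day 7 of culture than later (fitted median -3.10 from day 7 to day 22), where no mouse cell is present, and no biological difference other than the drug was tested.

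A hypothesis from the values is that genes of the amino acid response and of cholesterol synthesis alternate over the days. ASNS, ATF4, CHAC1, DDIT3, SESN2 and TRIB3, chosen after their values were seen, had a mean log2(CPM + 1) of 7.59 on day 7, 4.51 on day 9, 4.50 on day 10, 7.00 on day 14 and 7.66 on day 22, where 16 cholesterol synthesis genes had 4.95, 5.71, 5.56, 4.21 and 4.601. Over 7 days the Pearson correlation was -0.821 and the Spearman correlation -0.786, and without days 9 and 10 they were -0.397 and -0.50 (5 days), so the relation rests on those days. No p-value is given, because the genes were picked for this pattern on the same days. A tie within single cells is argued against, since the median Spearman correlation across the cells of a day was 0.083 (between -0.10 and 0.316). Medium changes and culture density may differ between the days and were not tested.

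The days were also put in 100 orderings, the real one included. With log time and the course term, the real count at an adjusted p under 0.05 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment was 0 genes, which 100 of 100 must reach, so that comparison decides nothing (highest other 61). At an unadjusted p under 0.05, 5 of 100 gave at least 1650 genes (highest other 1880), so chance cannot be excluded. With linear days and no course term, 1 of 100 gave 971 genes, the real one alone (highest other 343). These orderings also moved days between the courses, so they do not exclude chance for a fit chosen after the first was seen. That fit has no course term and course 1 holds the early days, so a difference between the courses stays open as a part of this count, which was 0.734% of the genes tested on linear days with the course term and 6.42% without it.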
